A study of Mus musculus with 28 samples.

How the data were processed

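Total RNA came from CD4 T cells sorted from thymus and spleen of male mice aged 6 to 8 weeks. Mice carried a Foxp3-gfp reporter allele that was either wild type (WT) or lacked conserved non-coding sequence 3, an enhancer of Foxp3 (labelled KO in the titles). The 28 libraries fell into 8 groups, with 3 WT and 4 KO libraries for each of 4 populations. These were thymic regulatory T (Treg) cells, thymic CD4 single-positive cells (CD4SP) and 2 splenic Treg populations that the titles call rTreg and aTreg. The titles do not expand r and a. Groups and replicate numbers came from the sample titles.

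Per the labels' protocols, RNA was extracted with TRIzol, cDNA was made with SMART amplification, and libraries were sequenced as read pairs on an Illumina HiSeq instrument. Per the submitters' processing notes, Trimmomatic, STAR and HTSeq were used with the mm10 build. Versions, settings and the gene annotation are not given in the sources used here. The deposited files hold the authors' raw HTSeq counts per gene symbol, not normalised, with separate lines for reads in no gene, ambiguous reads and reads that map to several places. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes may share reads. PCR duplicates cannot be recognised in such counts. Reads that map to several places were left uncounted by HTSeq as its output lines show, which lowers genes with near-identical copies.

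Each file listed 23420 gene symbols, of which 3712 had 0 counts in all libraries. Gene counts summed to between 2.20e+07 and 4.08e+07 per library. The lines that name no gene were kept out of library sizes and tests. Of the reads in genes, in no gene or ambiguous, 42.3 to 49.7% lay in no gene and 0.608 to 0.763% were ambiguous. Reads mapping to several places were 22.8 to 30.4% of all counted lines. Libraries of one group were compared in pairs by a chi-square test of their counts, and chi-square per degree of freedom was 7.31 to 39.6, so no pair agreed within sampling noise.

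Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalisation (factors 0.970 to 1.04) and the filterByExpr filter, which kept 13338 genes. All 28 libraries entered 1 fit with a mean per group and 20 residual degrees of freedom, so every contrast shared one estimate of the spread. The biological coefficient of variation was 12.7%. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Levels are CPM on TMM-scaled library sizes, given as mean ± SD. Fold changes are on the log2 scale with their standard errors (SE). The contrasts were KO against WT in each population, 3 contrasts between populations in WT mice, and 3 differences between KO effects.

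The lists of genes for T cell programmes, for other cell types and for handling stress were fixed, with the tests and the alternatives, before the data were examined. The 26 lists with at least 3 tested members were tested with camera from limma 3.58.1 at its preset inter-gene correlation of 0.01. They were tested again with a correlation estimated from the data, and with fry, which asks whether a list's genes move on balance one way. List p-values were adjusted by Benjamini-Hochberg within each comparison. For KO against WT this ran over 32 lists, the 26 and 6 made from these data, and for the other comparisons over the 26. Genes were named by a fixed rule. Foxp3 is named everywhere. In a comparison of 2 groups the rule takes the 6 largest rises and the 6 largest falls among genes past the test, with at least 8 CPM in the higher group and no overlap between the groups' libraries. It leaves out predicted genes, small RNAs and receptor segments. Rises and falls called largest in the results are the largest by this rule. It adds the 3 members of each list with the smallest p past the test, the 6 genes with the smallest p where fewer than 6 pass, and the 5 genes with the smallest p in a difference of effects. Genes outside that rule are marked as chosen after their values were seen.

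A fold against a group with 0 counts is a lower bound from 3 counts over the group, and a ratio to a group with few counts has a 95% Poisson interval on the lower count. These intervals and floors cover counting error only. Gene positions came from the GENCODE M21 annotation of the GRCm38 assembly, to which 21777 symbols matched directly and 1298 by an older symbol. The share of reads in no gene was compared between genotypes with a two-sided exact permutation test.

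The fits were tested on simulated counts drawn with the mean levels, dispersions and library sizes of these data and no other difference between groups, with 100 genes changed 1.5-fold and 100 changed 2-fold. KO against WT recovered 69 and 76 of these in thymic Treg cells, 59 and 74 in CD4SP cells, 56 and 70 in rTreg cells, and 54 and 79 in aTreg cells. The WT population contrasts recovered 59 and 73 (thymic Treg against CD4SP), 58 and 73 (aTreg against rTreg) and 64 and 72 (rTreg against thymic Treg). Differences between KO effects recovered 40 and 66 (thymic Treg minus CD4SP), 38 and 64 (aTreg minus rTreg) and 38 and 60 (rTreg minus thymic Treg). Unchanged genes called by mistake numbered 15, 5, 6 and 3 for KO against WT, in the order above. They numbered 6, 8 and 7 for the WT population contrasts and 8, 3 and 4 for the differences. The changed genes were drawn anew for each contrast, so recovery also varies with the draw.

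Alternatives were RLE normalisation, no low-count filter, the DESeq2 1.42.0 Wald test, fits of only the groups compared, limma voom with sample quality weights, a replicate block and leaving out each library. The block was the replicate number for KO against WT, and the number within each genotype for the other contrasts. The share of reads in no gene as a covariate, the myeloid marker sum as a covariate, leaving out KO thymic Treg libraries 1 and 2, and adjusting list p-values over the 26 lists alone were added after seeing the data. The labels do not say that the libraries come from separate animals, so p-values measure the spread between these samples, which may be partly technical.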

Results

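Transcript levels were measured by RNA-seq in 4 populations of CD4 T cells from mice with a WT Foxp3-gfp allele or with the same allele lacking enhancer CNS3 (KO). Foxp3 encodes the transcription factor that defines Treg cells. Each population had 3 WT and 4 KO libraries, with 2.20e+07 to 4.08e+07 counts in genes each. The design asks what loss of the enhancer changes in thymic Treg cells, in thymic CD4SP cells sorted as non-Treg, and in splenic rTreg and aTreg cells.

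Foxp3, on chromosome X from 7573644 to 7595245 on the plus strand (GRCm38), was counted in every library. In thymic Treg cells it stood at 544 ± 73.7 CPM in KO (SD, n = 4) and 652 ± 16.3 in WT (n = 3), a log2 fold change of -0.26 (SE 0.0869) that did not pass the edgeR quasi-likelihood test (adjusted p = 0.0561). Single libraries read 585, 446, 532 and 614 CPM in KO and 671, 643 and 642 in WT. In splenic rTreg cells the means were 547 ± 39.6 in KO and 618 ± 42.2 in WT (log2 fold change -0.18, adjusted p = 0.801), with single libraries at 508, 543, 602 and 536 against 614, 663 and 579. In aTreg cells they were 519 ± 24.0 and 612 ± 36.5 (log2 fold change -0.24, adjusted p = 0.556), with single libraries at 492, 520, 550 and 513 against 654, 587 and 595. In CD4SP cells Foxp3 fell by 1.25 on the log2 scale (SE 0.158, adjusted p = 8.27e-05), from 3.37 ± 0.131 to 1.44 ± 0.363 CPM. Those CD4SP libraries read between 1.07 and 1.91 CPM in KO (31, 53, 43 and 39 counts) and between 3.23 and 3.49 in WT (87, 134 and 130 counts). The deleted enhancer lies outside the exons, so exon counts do not check the deletion itself.

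**Figure D1:**
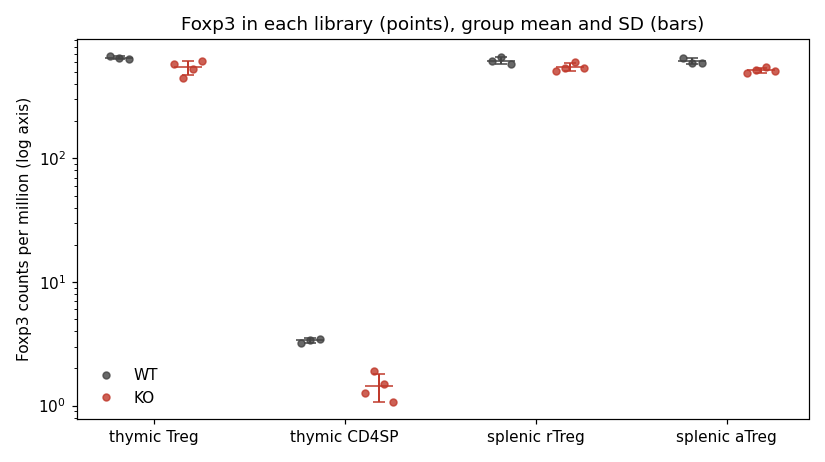
Foxp3 level in CPM (log axis) in each of the 28 libraries, by population and genotype, with group means and SDs. In CD4SP cells the 4 KO libraries lie between 1.07 and 1.91 CPM and the 3 WT libraries between 3.23 and 3.49.

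KO thymic Treg cells differed from WT in 1246 of 13338 genes, 562 higher and 684 lower. The largest rises included Gzmb, the cytotoxic protease granzyme B, at 33.1 ± 4.17 CPM in KO against 11.4 ± 0.876 in WT (log2 fold change 1.54, adjusted p = 0.00424). Cxcr3, a chemokine receptor of effector T cells, stood at 58.4 ± 4.94 against 25.5 ± 2.19 (1.19, adjusted p = 1.66e-04). The falls included Tgfbr3, a co-receptor for TGF-beta, at 13.4 ± 1.68 against 26.4 ± 0.838 (-0.97, adjusted p = 6.24e-06), and Satb1, a chromatin organiser of T cells, at 255 ± 19.8 against 365 ± 19.7 (-0.52, adjusted p = 8.12e-05). Most changes were small: the median size was 0.38 on the log2 scale, and 124 genes changed by more than 1. The other largest rises were Dnahc7a (an axonemal dynein chain, 2.83-fold), and, on the log2 scale, Lilrb4 (an inhibitory receptor, 1.44), Fcgrt (the neonatal Fc receptor, 1.31) and Cfp (properdin, 1.20). By the naming rule, which leaves out genes under 8 CPM or with overlapping groups, the other largest falls were Samd3 (-1.24), Xkrx (-1.14), Fibcd1 (-1.01), Pde3b (a cyclic nucleotide phosphodiesterase, -0.97) and Syp (synaptophysin, -0.97).

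Of 32 genes of activated Treg cells tested in KO thymic Treg cells, 19 rose, 0 fell and 13 did not pass the test (25 rose when adjusted over the list alone). The list was higher by camera (adjusted p = 1.29e-09; adjusted p = 0.174 with an estimated correlation). Examples were Icos, a co-stimulatory receptor (634 ± 33.0 against 454 ± 39.4 CPM, log2 fold change 0.48), Cxcr3 and Il1rl1, the IL-33 receptor (1.07). The Treg signature had 10 of 25 genes higher and 0 lower (13 and 1 adjusted over the list alone), among them Capg (0.63), Ecm1 (0.59) and the ectonucleotidase Nt5e (0.35). Its camera adjusted p was 2.73e-06 (adjusted p = 0.174 with an estimated correlation). Chemokine receptors and integrins had 7 of 29 higher and 0 lower (14 adjusted over the list alone), with Ccr8 at 0.42, at a camera adjusted p of 1.12e-04 (adjusted p = 0.174 with an estimated correlation). Cell cycle genes had 9 of 32 higher and 0 lower (21 adjusted over the list alone), including the replication licensing factors Mcm2 (0.38) and Mcm3 (0.40) and the mitotic kinase Plk1 (0.72). Their camera adjusted p was 1.54e-09 (adjusted p = 0.458 with an estimated correlation). Ribosomal protein genes had 2 of 79 higher, Rpl13 (0.28) and Rps2 (0.30), and 0 of them adjusted over the list alone. The camera adjusted p was 4.39e-09 (adjusted p = 0.466 with an estimated correlation).

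Of 20 resting T cell genes, 4 fell, 1 rose and 15 did not pass the test (7 lower and 3 higher adjusted over the list alone), with falls in Satb1, Bach2 (a repressor of effector differentiation, -0.39) and Foxp1 (-0.27). The camera adjusted p was 0.0249 (adjusted p = 0.528 with an estimated correlation). Immature thymocyte genes had 3 of 19 lower and 0 higher (3 and 1 adjusted over the list alone), namely Themis, a regulator of thymocyte selection (-0.47), Bcl6 (-0.47) and Cd1d1 (-0.24), at a camera adjusted p of 0.0152 (adjusted p = 0.466 with an estimated correlation). Apoptosis regulators moved both ways, with 2 of 22 higher and 4 lower, the same adjusted over the list alone. They included the pro-apoptotic Bcl2l11 (-0.49) and the caspase inhibitor Cflar (-0.31). Helper T cell genes had 1 of 19 higher, Il18r1, the IL-18 receptor (105 ± 14.2 against 61.3 ± 7.35 CPM, 0.77), and 2 lower, Eomes (-1.47) and Bcl6; adjusted over the list alone, 2 rose and 2 fell. NF-kB genes had 3 of 24 higher and 2 lower, with Tnfrsf4 at 0.31, Tnfrsf18 at 0.29 and Birc3 at -0.24. Interferon-stimulated genes had 2 of 32 higher, Gbp3 (0.47) and Oas1a (0.52), and 2 lower. Adjusted over the list alone, NF-kB genes had 4 higher and 2 lower, and interferon-stimulated genes 2 and 2. Camera called none of these last lists (adjusted p = 0.590 for apoptosis, 0.497 for helper, 0.194 for NF-kB and 0.522 for interferon genes).

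Markers of other cells were also counted in these libraries. Myeloid markers summed to 797 ± 309 CPM in KO thymic Treg libraries and 391 ± 72.7 in WT, with 4 of 15 past the test, all higher (10 adjusted over the list alone), including Itgam (1.58, with overlapping groups), Fcgr3 (1.17) and Cst3 (0.43). Their camera adjusted p was 0.00108 (adjusted p = 0.466 with an estimated correlation). B cell markers summed to 849 ± 188 against 574 ± 84.5 CPM, with KO library 2 at 572, within the WT range. Of 14 B cell markers 0 were higher and 1, Cr2 (-1.40), was lower past the test (1 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.0884). CD8 T cell markers summed to 507 ± 36.4 against 347 ± 26.0 CPM. Of 7 CD8 markers 1 was higher, Ccl5 (0.96), and 1 lower, Eomes (-1.47), the same adjusted over the list alone. Col3a1, a stromal collagen, had 215 counts in KO and 12 in WT, a ratio of 15.9 (95% counting interval 9.09 to 30.7), with overlapping groups. It was the 1 of 8 stromal and epithelial markers past the test (2 higher and 1 lower adjusted over the list alone). They summed to 275 ± 24.0 CPM in KO and 321 ± 25.5 in WT. The list was not called by camera (adjusted p = 0.0531; adjusted p = 0.174 with an estimated correlation) and was higher by fry (adjusted p = 0.00592). Fosb, an immediate-early gene of the handling stress list, rose by 1.38, while that list summed to 2192 ± 111 CPM in KO and 2203 ± 159 in WT. The share of reads in no gene was 43.1 ± 1.27% in KO and 47.5 ± 1.55% in WT (difference -4.43 points). Its two-sided exact permutation p was 0.0571 over 35 arrangements, and 0.229 after Benjamini-Hochberg adjustment over 4 populations. With 3 and 4 libraries the KO and WT values do not overlap, and 0.0571 is the value reached by this full separation.

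Of the 26 lists, 6 were called higher and 2 lower in KO thymic Treg cells by camera, 0 held with an estimated correlation, and 5 passed fry (4 adjusted over the 26 lists alone, without the cell cycle). The count of 1246 genes became 45 with the share of reads in no gene as a covariate, 520 with the myeloid sum as a covariate, and 450 without KO libraries 1 and 2, which had most myeloid counts. It was 497 without WT library 1, 546 without WT library 2 and 766 without KO library 3. With either covariate, or without KO libraries 1 and 2, most lists also had fewer members past the test.

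A comparison with activation in the spleen used genes picked from WT splenic cells, so it is not independent of these samples. Of the 1364 genes more than 1 log2 unit higher in WT aTreg than in WT rTreg cells, 166 rose and 1 fell in KO thymic Treg cells (adjusted p = 0.0874 by camera with an estimated correlation). Of the 436 genes lower in aTreg cells by that margin, 4 rose and 71 fell (adjusted p = 0.0217 with an estimated correlation). Between the KO effect in thymic Treg cells and the aTreg against rTreg contrast, 816 genes passed both tests, and 771 of these went the same way.

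**Figure D2:**
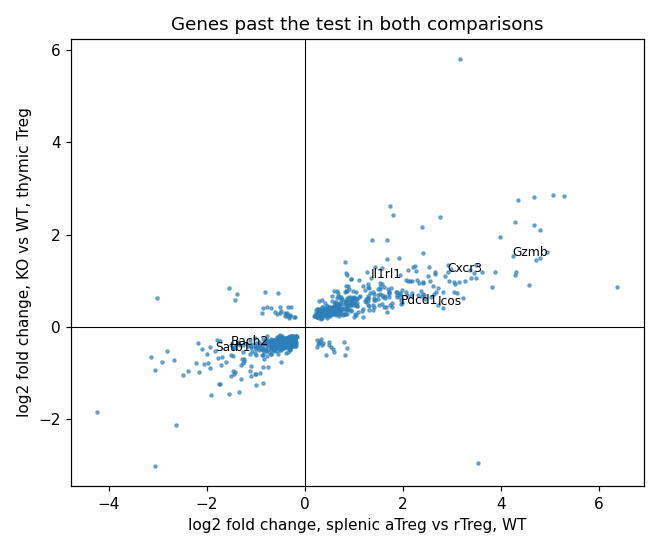
Log2 fold change of KO against WT in thymic Treg cells plotted against log2 fold change of aTreg against rTreg in WT spleen, 1 point for each of the 816 genes past both tests. Of these, 771 lie where both changes have the same sign.

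KO thymic CD4SP cells differed from WT in 26 genes, 22 higher and 4 lower. The rises included Rgs1, a regulator of G protein signalling, at 31.2 ± 7.75 CPM in KO against 14.1 ± 2.34 in WT (log2 fold change 1.14, adjusted p = 8.27e-05). Several genes of Treg cells rose while Foxp3 fell by 1.25. Il2ra, the IL-2 receptor alpha chain, stood at 48.4 ± 56.4 against 9.24 ± 2.04 (2.38), and Ikzf2, the transcription factor Helios, at 102 ± 31.8 against 56.2 ± 13.5 (0.85). Lrrc32, which holds latent TGF-beta on the cell surface, stood at 1.41 ± 0.324 against 0.310 ± 0.206 (2.25, adjusted p = 8.27e-05). Other named rises were Jun (1.43), Gsta4 (0.75) and Lad1 (0.76). Ccdc22, the gene next to Foxp3, fell by 0.67, from 23.6 ± 1.71 to 14.8 ± 1.18.

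Of 25 Treg signature genes tested in CD4SP cells, 6 rose and 1, Foxp3, fell (12 and 1 adjusted over the list alone). The 6 were Il2ra, Ikzf2, Lrrc32, Cd83 (0.91), Ctla4 (an inhibitory receptor, 0.68) and Tnfrsf9 (0.54). Camera called the list higher (adjusted p = 2.88e-12; adjusted p = 0.0519 with an estimated correlation). NF-kB genes had 2 of 24 higher, Cd83 and Tnfrsf9 (4 adjusted over the list alone), at an adjusted p of 6.10e-04 (adjusted p = 0.0519 with an estimated correlation). TCR-induced early genes had 2 of 24 higher, Ctla4 and Tnfrsf9 (4 adjusted over the list alone), at 0.00127 (adjusted p = 0.0768 with an estimated correlation). IL-2 and STAT5 genes had 2 of 18 higher, Il2ra and Cish (0.58), also 2 adjusted over the list alone, at 0.0300 (adjusted p = 0.174 with an estimated correlation). The activated Treg list and the chemokine receptor list each had 1 gene higher, Ccr6 (2.47), of 32 and 29 tested (1 and 3 adjusted over the list alone). Their adjusted p was 0.0375 and 0.0241 (adjusted p = 0.590 and 0.392 with an estimated correlation). KO library 2 lay far from the other KO libraries for Ccr6, at 5.77 CPM. Genes near Foxp3 were the list called lower, with 1 of 25 past the test, Ccdc22, and 2 adjusted over the list alone (adjusted p = 3.84e-04; adjusted p = 0.0519 with an estimated correlation).

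One KO CD4SP library, number 2, stood apart from the other 3. It had 15649 genes detected and summed marker levels of 298 CPM for B cells, 300 for myeloid cells, 700 for dendritic cells and 250 for CD8 T cells. WT means of these sums were 66.5 ± 13.3, 99.5 ± 7.56, 275 ± 54.4 and 104 ± 5.30. Its Il2ra level was 133 CPM. B cell markers (0 of 14 past the test, adjusted p = 0.00216) and dendritic cell markers (0 of 10, adjusted p = 0.0113) were called higher as lists (adjusted p = 0.421 and 0.392 with an estimated correlation). So were immature thymocyte genes (0 of 19, adjusted p = 7.11e-04), cell cycle genes (0 of 32, adjusted p = 0.0292), histones (0 of 36, adjusted p = 8.06e-04) and handling stress genes (1 of 17, Jun, adjusted p = 0.0154). With an estimated correlation their adjusted p was 0.347, 0.631, 0.392 and 0.392. Adjusted over the list alone, 4, 0, 1 and 4 of them were higher. Of the 26 lists, 12 were higher and 1 lower, 0 held with an estimated correlation and 3 passed fry (4 adjusted over the 26 lists alone, with TCR-induced early genes). Without library 2, 22 genes passed the test, and 4 of the 6 raised Treg signature genes stayed past it: Cd83, Ikzf2, Il2ra (1.12) and Lrrc32 (2.10). Ctla4 went from 0.68 to 0.48 (adjusted p = 0.0948) and Tnfrsf9 from 0.54 to 0.46 (adjusted p = 0.173). The count was 0 when only the CD4SP libraries were fitted in edgeR (828 genes had unadjusted p under 0.05 in the fit of all libraries), 63 with DESeq2, 7 with voom and 15 without WT library 2.

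KO splenic rTreg cells differed from WT in 18 genes, 11 higher and 7 lower. The rises included receptors for IL-1 family cytokines that lie side by side on chromosome 1. Il18r1 stood at 47.5 ± 3.63 CPM in KO against 26.3 ± 2.29 in WT (log2 fold change 0.85, adjusted p = 1.84e-04), and Il1rl1 at 17.0 ± 1.37 against 9.03 ± 1.65 (0.91, adjusted p = 0.0320). The chemokine receptor Ccr8 rose from 27.8 ± 1.76 to 43.7 ± 8.38 (0.65), and Dnahc7a from 14.5 ± 0.735 to 31.8 ± 3.50 (1.13). Gucy1b3, a guanylate cyclase subunit (1.01), and Fsd1l (0.85) also rose. The 6 largest falls by the naming rule were Syp (-1.26, adjusted p = 6.78e-04), the tubulin Tubb2a (-0.70), Ahdc1 (-0.48), the glucosylceramide synthase Ugcg (-0.40), Zfp120 (-0.38) and Pptc7 (-0.37).

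Activated Treg genes had 2 of 32 higher in KO rTreg cells, Ccr8 and Il1rl1, and 0 lower (3 and 1 adjusted over the list alone). The camera adjusted p was 2.48e-04 (adjusted p = 0.487 with an estimated correlation). Chemokine receptors had 1 of 29 higher, Ccr8, at 0.0183 (3 adjusted over the list alone; adjusted p = 0.487 with an estimated correlation). Helper T cell genes had 1 of 19 higher, Il18r1, and were not called (adjusted p = 0.416). Handling stress genes had 0 of 17 past the test (3 adjusted over the list alone) and were called higher at 8.42e-05 (adjusted p = 0.297 with an estimated correlation). Their sums were 3806, 3643, 4559 and 4843 CPM in KO libraries 1 to 4, against 3475 to 3810 in WT. Only KO libraries 3 and 4 lay above WT. Histones had 0 of 36 past the test (2 adjusted over the list alone) at 1.75e-07 (adjusted p = 0.297 with an estimated correlation). Treg signature, cell cycle and ribosomal lists, each with 0 members past the test, were called higher at 0.00375, 0.0143 and 0.0345 (adjusted p = 0.487, 0.743 and 0.754 with an estimated correlation). Resting genes (0 of 20) and genes near Foxp3 (1 of 25, Syp, lower; 3 adjusted over the list alone) were called lower, both at 0.0240 (adjusted p = 0.548 and 0.380 with an estimated correlation). Of the 26 lists, 0 passed fry. The count of 18 became 48 with DESeq2 and 43 with voom. It was 6, 7 and 9 without WT libraries 1, 2 and 3, and 8, 9 and 7 without KO libraries 1, 2 and 4.

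KO splenic aTreg cells differed from WT in 4 genes. Dnahc7a rose from 13.1 ± 0.934 to 25.2 ± 1.37 CPM (log2 fold change 0.95, adjusted p = 0.0106), Fsd1l from 3.60 to 7.88 (1.13, SE 0.194, adjusted p = 0.0195), and the transcription factor Klf6 from 328 ± 42.9 to 478 ± 45.2 (0.54, adjusted p = 0.0273). Capn11, a calpain protease, had 2 counts over the KO libraries against 147 in WT, a ratio of 91.3 (95% counting interval 25.3 to 754). The next genes by p did not pass: Pspc1 (0.47, adjusted p = 0.0634) and Ikzf4, the transcription factor Eos (202 ± 7.95 against 146 ± 24.3 CPM, adjusted p = 0.0691). Cell cycle genes (0 of 32 past the test) and myeloid markers (0 of 15) were called lower as lists, at 6.06e-07 and 0.00675 (adjusted p = 0.888 and 0.911 with an estimated correlation). Myeloid markers summed to 289 ± 26.1 CPM in KO and 413 ± 63.1 in WT. Handling stress genes (0 of 17, 6 adjusted over the list alone) and histones (0 of 36) were called higher, at 0.00102 and 0.00605 (adjusted p = 0.888 for both with an estimated correlation). Handling stress sums were 3428, 3248, 4038 and 4007 CPM in KO libraries 1 to 4, against 3205 to 3275 in WT. They were highest in KO libraries 3 and 4. The count of 4 became 15 with DESeq2, 7 with only the aTreg libraries, 46 with voom, and 13 with the share of reads in no gene as a covariate. It was 0 without WT library 2, 2 without WT library 3 or without KO libraries 1, 2 or 3 in turn, and 1 without KO library 4.

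Some KO effects recurred between populations. Thymic Treg and rTreg cells shared 16 genes, 9 higher and 7 lower, where independent lists would share 0.463 and 0.359. These values assume that the libraries of different populations are independent, which the labels do not settle, and deviations shared between libraries would raise the overlap given by chance. Il18r1, Il1rl1, Ccr8, Gucy1b3 and Dnahc7a were among those higher in both, and Syp, Tubb2a, Ugcg and Pptc7 among those lower in both. Thymic Treg and CD4SP cells shared 9 genes, 7 higher and 2 lower (0.927 and 0.205 by independent lists), including Rgs1, Cd83 and Cish. Across 13338 genes, which are not independent replicates, the fold changes of thymic Treg and rTreg cells had a Pearson correlation of 0.228 and a Spearman correlation of 0.298. In all, 24 genes changed the same way in at least 2 populations and 5 in at least 3. Chosen after their values were seen, those 5 are Capn11, Dnahc7a, Fsd1l, Klf6 and Zcchc18. Capn11, on chromosome 17, was lower in all 4 populations, and the KO libraries numbered 1, 2 and 4 had 0 counts of it in each population. KO number 3 had 10, 4, 4 and 2 counts in thymic Treg, CD4SP, rTreg and aTreg cells.

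Of 41 tested genes within 5 Mb of Foxp3, 7 passed the test in at least 1 population, some lower and others higher in KO. Ebp, a sterol isomerase taken as an example after the values were seen, was higher in thymic Treg cells (0.31, adjusted p = 0.0124). Ppp1r3f, 4930524L23Rik, Ccdc22 and Syp were singled out after their values were seen to be lower. Ccdc22 (X, 7593809 to 7605517, minus strand) changed by -0.38 in thymic Treg cells (adjusted p = 0.0495), -0.67 in CD4SP cells (0.00610), -0.55 in rTreg cells (0.0577) and -0.47 in aTreg cells (0.400). Syp (X, 7638471 to 7653256, plus strand) changed by -0.97, -0.84, -1.26 and -0.71, with adjusted p of 0.00153, 0.316, 6.78e-04 and 0.325. 4930524L23Rik changed by -0.88 in CD4SP cells (adjusted p = 0.00115). Ccdc22 shares 1437 bases with Foxp3 on the opposite strand, and 4930524L23Rik and Ppp1r3f overlap Foxp3 as well, so their counts are uncertain. Syp starts beyond the end of Foxp3. Prickle3 and Plp2, which begin 83.6 and 94.3 kb from the start of Foxp3, did not pass the test in any population.

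**Figure D3:**
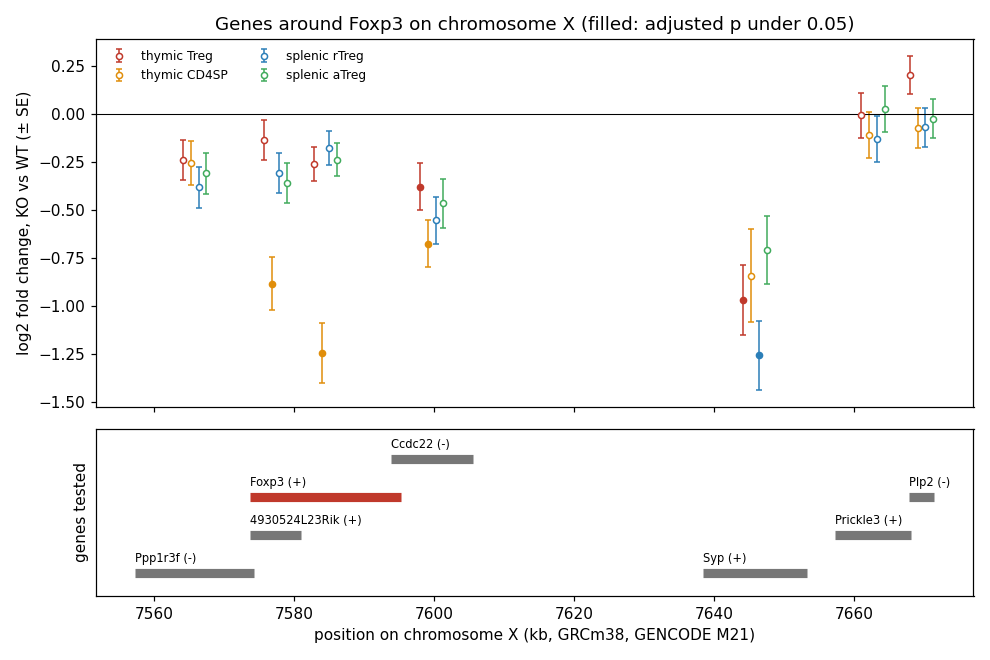
Log2 fold change of KO against WT (points, ± SE) for Foxp3 and 6 neighbouring genes in 4 populations, above their positions on chromosome X (GRCm38), with filled points for adjusted p under 0.05. Syp reads -0.97 in thymic Treg cells and -1.26 in rTreg cells, and Prickle3 reads -0.01 and -0.13.

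The KO effects in thymic Treg and CD4SP cells differed in 82 genes, 42 more positive and 40 more negative in Treg cells. Foxp3 was among them: its effect was 0.98 log2 units less negative in Treg than in CD4SP cells (adjusted p = 0.00511). The cells were sorted as Treg or non-Treg, which bears on Foxp3 itself, and its CD4SP level was only 1.44 CPM in KO and 3.37 in WT. The difference therefore does not measure the enhancer's effect on Foxp3 apart from the sort. Atp6v0a1, a proton pump subunit, changed by -0.44 in Treg and 0.81 in CD4SP cells (difference -1.24, adjusted p = 7.69e-04), and Lrrc32 by 0.12 and 2.25 (difference -2.13). Prr13 (0.65 and -0.02), Cdca7l (0.61 and -0.03) and Syngr2 (0.65 and 0.02) had their effect on the Treg side. Activated Treg genes (1 of 32 higher, 1 lower), cell cycle genes (0 of 32), maturation genes (0 of 14) and ribosomal genes (0 of 79) had a more positive effect in Treg cells by camera, at 3.00e-05, 3.00e-05, 0.0335 and 1.14e-05. Immature thymocyte genes (0 of 19 higher, 1 lower, 11 lower adjusted over the list alone) had a more negative one at 3.77e-05. With an estimated correlation these adjusted p were 0.818, 0.866, 0.818, 0.866 and 0.818, and 0 lists passed fry. The count of 82 became 325 with DESeq2, 164 with voom and 32 with only the 4 groups compared. It was 43 without WT Treg library 1, 51 without WT Treg library 2, 40 without WT CD4SP library 2, 162 without KO Treg library 4 and 125 without KO CD4SP library 2.

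The KO effects in rTreg and thymic Treg cells differed in 4 genes. Ly6a, a surface antigen of activated lymphocytes, changed by -0.20 in rTreg and 0.93 in thymic Treg cells (difference -1.13, adjusted p = 0.00126). The protease Lgmn changed by -0.09 and 0.72, the glutaredoxin Glrx by -0.03 and 0.68, and Lypd6b by 0.11 and -1.41 (adjusted p = 0.0281). Syngr2 did not pass (difference -0.47, adjusted p = 0.0532), nor did Foxp3 (0.08, adjusted p = 0.854). Lists of Treg signature, activated Treg, cell cycle, maturation, myeloid and ribosomal genes, each with 0 members past the test, had a less positive effect in rTreg cells by camera. Their adjusted p was 0.00559, 2.46e-04, 4.05e-05, 0.0143, 3.80e-04 and 4.05e-05, and 0.743, 0.743, 0.763, 0.743, 0.743 and 0.768 with an estimated correlation. The count of 4 became 7 without the low-count filter, 74 with DESeq2 and 17 with voom. It was 8 without KO thymic Treg library 2, 16 without KO thymic Treg library 4 and 25 without WT rTreg library 3.

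The KO effects in aTreg and rTreg cells differed in 0 genes by edgeR, with 617 at unadjusted p under 0.05, 1 gene by DESeq2 and 0 by voom. The smallest p belonged to Ccr8 (difference -0.71, adjusted p = 0.581), Ctsz (-0.35), Phf1 (0.59), Ptgfrn (1.45) and Trim8 (0.43), none past the test, and Foxp3 differed by -0.06. Activated Treg genes (0 of 32) and cell cycle genes (0 of 32) had a more negative effect in aTreg cells by camera, at 1.97e-05 and 2.84e-09 (adjusted p = 0.782 for both with an estimated correlation). Without KO rTreg library 1 the count was 1.

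In WT mice, thymic Treg cells differed from CD4SP cells in 6447 genes, 3568 higher and 2879 lower in Treg cells. Foxp3 stood at 652 ± 16.3 against 3.37 ± 0.131 CPM, 193-fold higher. Lrrc32 stood at 310.3 against 0.310 (log2 fold change 10.04, SE 0.188), and Il1r2, a decoy receptor for IL-1, at 144 ± 18.1 against 0.194 ± 0.163 (9.66). Tff1, a trefoil peptide, had 1546 counts in Treg cells and 0 in CD4SP cells, at least 516-fold higher over the group. Gbp1, an interferon-induced GTPase, had 3414 counts against 2, a ratio of 1709 (95% counting interval 473 to 14111). Peli2 had 1221 against 1, a ratio of 1222 (219 to 48281), and Ptrf, a caveola component, 8881 against 6. The largest falls were Pdlim4 (-5.81), Adamts14 (-5.73), Ggt5 (-5.14), Nacc2 (-4.74), Igfbp4 (-4.35) and Hs3st3b1 (-4.18).

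All 25 Treg signature genes were higher in WT thymic Treg cells, including Nt5e (4.14), at a camera adjusted p of 4.53e-04 with an estimated correlation. Activated Treg genes had 30 of 32 higher and 1 lower (adjusted p = 0.0174 with an estimated correlation), and NF-kB genes 20 of 24 higher and 0 lower (1.17e-04), such as Tnfrsf4 (3.72), Tnfrsf18 (2.72) and Cd83 (6.55). TCR-induced early genes had 19 of 24 higher and 1 lower (0.00176), with Dusp4 at 5.66. Apoptosis regulators had 18 of 22 higher and 2 lower (0.0174), among them Pmaip1 (4.11) and Bcl2l1 (1.61). Lists of IL-2 and STAT5 genes (12 of 18 higher, 4 lower), helper T cell genes (13 of 19 higher, 2 lower) and chemokine receptors (19 of 29 higher, 4 lower) also held with an estimated correlation (adjusted p = 0.0143, 0.0275 and 0.0448). Cell cycle genes had 25 of 32 lower and 0 higher, with Top2a at -1.45 (adjusted p = 2.73e-06; adjusted p = 0.426 with an estimated correlation). Counts adjusted over the list alone were 25, 30, 20, 19, 18, 12, 13 and 19 higher for these lists in that order, and 25 lower for the cell cycle. The lower counts were unchanged but for 2 activated Treg genes. Myeloid markers had 12 of 15 higher in Treg cells (12 adjusted over the list alone), including C1qb (5.29), and summed to 391 ± 72.7 CPM against 99.5 ± 7.56 (adjusted p = 2.70e-04; adjusted p = 0.378 with an estimated correlation). B cell markers summed to 574 ± 84.5 CPM against 66.5 ± 13.3. Of the 26 lists, 11 were higher and 5 lower by camera, 8 held with an estimated correlation and 20 passed fry.

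In WT spleen, aTreg cells differed from rTreg cells in 5060 genes, 2650 higher and 2410 lower in aTreg cells. Foxp3 read 612 ± 36.5 against 618 ± 42.2 CPM (log2 fold change -0.02, adjusted p = 0.920). Icos stood at 2014 ± 120.3 against 308 ± 29.0 CPM (2.71) and Ccr8 at 196 ± 19.6 against 27.8 ± 1.76 (2.82). The anti-apoptotic Bcl2 stood at 209 ± 10.6 against 804 ± 51.1 (-1.94). The largest rises were Nckap5 (6.85), Arnt2 (5.72), Prune2 (5.64), P2ry13 (5.20), Ky (5.07) and Cd5l (5.07). The largest falls were Acvr1c (-4.11), Ly6c1 (-3.29), Adcy6 (-3.14), Selp (-3.12), Myo6 (-3.02) and Ampd1 (-3.02).

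Activated Treg genes were higher in aTreg cells in 30 of 32 cases and lower in 0, and resting genes lower in 18 of 20 and higher in 1 (adjusted p = 0.0112 for both with an estimated correlation; the same counts adjusted over the list alone). IL-2 and STAT5 genes had 12 of 18 lower and 0 higher, including Stat5a (-0.63), with 13 lower adjusted over the list alone (adjusted p = 0.0112 with an estimated correlation). Cell cycle genes had 29 of 32 higher and 0 lower, including Mki67 (1.82) and Rrm2 (1.72), also 29 adjusted over the list alone (adjusted p = 3.76e-13; adjusted p = 0.261 with an estimated correlation). Ribosomal protein genes had 55 of 79 lower and 2 higher (59 and 2 adjusted over the list alone), at 9.99e-13 (adjusted p = 0.321 with an estimated correlation). Myeloid markers had 12 of 15 higher (12 adjusted over the list alone) and summed to 413 ± 63.1 against 128 ± 5.48 CPM (adjusted p = 2.02e-05; adjusted p = 0.292 with an estimated correlation). B cell marker sums were 1204 ± 404 against 426 ± 81.2 CPM. Of the 26 lists, 9 were higher and 5 lower by camera, 3 held with an estimated correlation and 19 passed fry.

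Between organs in WT mice, splenic rTreg cells differed from thymic Treg cells in 4081 genes, 1850 higher and 2231 lower in the spleen. Foxp3 read 618 ± 42.2 against 652 ± 16.3 CPM (-0.08, adjusted p = 0.576). Fos, an immediate-early transcription factor, stood at 298 ± 12.4 against 14.2 ± 3.42 (log2 fold change 4.38), with Fosb (3.41), Ly6c1 (4.06), Myo6 (3.51) and Klf4 (3.24) also higher. Bpifa2 had 844 counts in spleen and 0 in thymus, at least 299-fold higher over the group, with an SD near its mean (9.15 ± 8.04 CPM, adjusted p = 0.0461). Rag1, the recombinase of developing lymphocytes, had 0 counts in spleen and 953 in thymus, at least 299-fold lower in spleen. Tff1 had 1 count against 1546, a ratio of 1454 (95% counting interval 261 to 57445). Fn1 (-7.57), Alox15 (-6.66), Slpi (-4.90) and Scin (-4.79) completed the largest falls.

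Immature thymocyte genes had 13 of 19 lower in rTreg cells and 0 higher (the same adjusted over the list alone), including Sox4 (-1.90) and Tox (-0.93), at a camera adjusted p of 7.16e-06 (adjusted p = 0.167 with an estimated correlation). Maturation and egress genes had 9 of 14 higher and 2 lower (10 and 2 adjusted over the list alone), including Il7r (0.74) and Itgb7 (0.71), at 3.57e-04 (adjusted p = 0.167 with an estimated correlation). Handling stress genes had 9 of 17 higher and 2 lower, the same adjusted over the list alone, with Junb at 2.33 and Zfp36 at 1.95 (adjusted p = 2.86e-05; adjusted p = 0.167 with an estimated correlation). Cell cycle genes had 21 of 32 lower and 0 higher (23 adjusted over the list alone; adjusted p = 5.18e-05; adjusted p = 0.491 with an estimated correlation). Ribosomal protein genes had 45 of 79 higher and 0 lower (48 and 1 adjusted over the list alone; adjusted p = 1.89e-10; adjusted p = 0.401 with an estimated correlation). Myeloid markers had 11 of 15 lower (11 adjusted over the list alone) and summed to 128 ± 5.48 against 391 ± 72.7 CPM (adjusted p = 6.51e-05; adjusted p = 0.397 with an estimated correlation). Of the 26 lists, 6 were higher and 8 lower by camera, 0 held with an estimated correlation and 19 passed fry.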

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

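The tests of the share of reads in no gene, of marker genes, of activated cells, of Foxp3 and Treg-prone cells, of single libraries and of linked DNA were chosen after the results were seen, and the tests of other splits of the samples were chosen before. Of 138 groups of 4 libraries examined for a library far from the others, 18 had one, where chance gives about 1 in 20.

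Among KO thymic Treg libraries, number 4 lay far from the others with 45.0% of reads in no gene, 257 CPM of Ccl5, 1.27 of Cr2 and 126 of Il18r1. Library 3 lay apart for Birc3 (222 CPM), and library 2 for Capg (410) and Mcm2 (74.8). KO CD4SP library 2 lay apart in summed markers of B cells (298 CPM), plasma cells (107), myeloid cells (300), dendritic cells (700), CD8 T cells (250) and NK cells (149), and in Ccr6 (5.77), Il2ra (133) and Lad1 (13.4). KO CD4SP library 4 lay apart for Ccdc22 (16.5 CPM), and KO aTreg library 3 for Capn11 (0.0839), the others being at 0.

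KO effects that differed between thymic Treg and CD4SP cells, by a test of the difference, were those of Atp6v0a1 (-1.24), Cdca7l (0.642), Foxp3 (0.984), Lrrc32 (-2.13), Prr13 (0.668) and Syngr2 (0.627). Between rTreg and thymic Treg cells they were those of Glrx (-0.706), Lgmn (-0.806), Ly6a (-1.13) and Lypd6b (1.52).

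Other splits of the libraries bear on the counts of genes. Only 1 of 35 splits, the real one, reached the count in thymic Treg cells (1246 genes, highest other 1107). The same held for rTreg cells (18, highest other 2) and aTreg cells (4, highest other 3). That is the smallest share 35 splits allow, and it was not adjusted over the 4 populations. The splits also take WT and KO libraries as independent, which is not known, so they do not exclude chance. In aTreg cells the count was 0 without WT library 2. Chance is not excluded for CD4SP cells either (26 genes, highest other 101, 7 of 35 splits as large). Nor is chance excluded for the difference rTreg minus thymic Treg (4 genes, highest other 108, 3 of 30). The count of 101, several times the real one, came from a split that gave the WT label to KO CD4SP libraries 1 and 2. Every other CD4SP split with more than 26 genes also gave that label to KO library 2, which stood apart. Some splits that did so had fewer genes. The split with 108 genes exchanged WT and KO in thymic Treg cells for all libraries but KO library 2, and another, with 70 genes, left the thymic Treg groups in place, so both hold most or all of the thymic genotype contrast. For thymic Treg minus CD4SP, 2 of 30 splits reached 82 genes (highest other 82), so chance is not excluded by their share. The 1 other split that reached it kept the CD4SP groups and exchanged WT and KO in thymic Treg cells for all libraries but KO library 2, so it is near a mirror image and still holds most of the genotype contrast. The split with 1107 genes is of the same kind, with KO library 4 left in place. For aTreg minus rTreg the real count is 0, which all 30 of 30 splits reach by construction (highest other 17), so the splits say nothing there; edgeR gave 617 genes at unadjusted p under 0.05, DESeq2 gave 1 gene and voom 0. For the 3 contrasts between WT populations the 10 splits are too few for a share under 0.05 (6447, 5060 and 4081 genes, highest other 0 in each, 1 split as large).

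The first pattern is the many genes past the test between KO and WT thymic Treg cells. Whether myeloid cells in the KO sort were the whole cause was not settled. With the marker sum as a covariate, 88.7% of the median change of the raised genes was left (0.45 before, 0.40 after). The range was 0.38 to 0.41 leaving out single thymic Treg libraries, and genes past the test fell to 520. All 28 libraries shared the same slope on the marker sum. KO CD4SP library 2, at 300 CPM against 87.6 to 105 in the other KO CD4SP libraries, was kept in every such fit. That slope need not hold for the thymic Treg sort, so the fit cannot decide. A difference in the share of reads in no gene cannot be told apart from genotype: 68.0% of the median change was left (0.38 before, 0.26 after), the median SE went from 0.0926 to 0.131, and 45 genes passed, since the share is lower in every KO thymic Treg library. A larger share of activated cells may contribute. Of the 816 genes past both tests, 94.5% went the same way in aTreg against rTreg cells. Myeloid sums (413 against 128 CPM) and cell cycle sums (2167 against 1112) were also higher in aTreg than in rTreg cells of WT mice. In KO thymic Treg cells both were higher than in WT (797 against 391 and 1987 against 1515). The agreement therefore does not single out activated cells.

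The second pattern is the rise of Treg signature genes in KO CD4SP cells. More Treg cells with the Foxp3 level of the sorted KO Treg cells are argued against by Foxp3 itself. It changed by -1.25 on the log2 scale in CD4SP cells and by -0.26 in thymic Treg cells. Foxp3 is the gene whose enhancer was removed, so its level does not speak to Treg cells with less Foxp3. The library that stood apart, with its markers of other cells, is argued against as the sole source: 4 of the 6 raised signature genes passed without it, and KO libraries 1, 3 and 4 had marker sums near those of WT (60.5 to 81.8 against 51.8 to 77.6 CPM for B cells, 87.6 to 105 against 94.2 to 108 for myeloid cells). Treg-prone cells left in the Foxp3-negative gate stay open and cannot be told apart from other sources of these genes, and the count of genes was not beyond that of other splits. Of the 22 raised genes, found with library 2 included, 95.5% were higher in KO thymic Treg than in KO CD4SP cells (50.9% of all genes tested), but so were markers of B cells (median log2 fold change 2.44) and of myeloid cells (3.57), so this share does not single out Treg-prone cells.

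The third pattern is the genes changed in the same direction in several populations. DNA linked to the altered allele may account for part of it: 2 of the 24 shared genes, Ccdc22 and Syp, lie within 5 Mb of Foxp3, where the share of genes would give 0.0744. That covers 2 genes only. They start 20.2 and 64.8 kb from the start of Foxp3, so their position cannot tell linked DNA apart from a local effect of the deletion. Lower Foxp3 acting in each population cannot be told apart from other causes, as 2 of the 5 genes changed in at least 3 populations passed the test in CD4SP cells, where Foxp3 is low, and 5 is too few to decide.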

How the results depend on the processing

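The covariate fits, the fit without KO thymic Treg libraries 1 and 2 and the adjustment over the 26 lists alone were chosen after the results were seen. The 3 contrasts between WT populations stayed within 1.5 times of their counts under every alternative run, as did all counts with RLE normalisation. The thymic Treg count of 1246 became 45 with the share of reads in no gene as a covariate, 520 with the myeloid covariate and 450 without libraries 1 and 2, and ranged from 497 to 1699 leaving out single libraries. Fewer libraries, or a covariate that runs with genotype, lower the power of these fits. In the first of them Itpr2 reversed to 0.0198 (adjusted p = 0.983), and its cause was not tested.

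DESeq2 gave 63 genes in CD4SP, 48 in rTreg and 15 in aTreg cells, and 325, 1 and 74 for the differences thymic Treg minus CD4SP, aTreg minus rTreg and rTreg minus thymic Treg. Shared genes with DESeq2 were 22 for thymic Treg and CD4SP, 31 for thymic Treg and rTreg, 7 for thymic Treg and aTreg, 5 for CD4SP and rTreg, and 0 for CD4SP and aTreg. Voom gave 7 in CD4SP, 43 in rTreg, 46 in aTreg, 164 for thymic Treg minus CD4SP and 17 for rTreg minus thymic Treg. With only the groups compared the counts were 0 in CD4SP cells by edgeR (828 at unadjusted p under 0.05 with all libraries), 7 in aTreg cells and 32 for thymic Treg minus CD4SP. No low-count filter gave 7 for rTreg minus thymic Treg, and the share of reads in no gene as a covariate gave 13 in aTreg cells. The cause of these changes was not tested.

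Leaving out single libraries gave 15 to 35 genes in CD4SP cells, 6 to 14 in rTreg and 0 to 6 in aTreg cells. For the differences of KO effects it gave 40 to 162, 0 to 1 and 3 to 25.

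The labels do not say what the replicate numbers share, and the numbers were not used as pairs in the main fits. Libraries of one number and genotype in different populations deviated together at a median correlation of 0.104 (-0.004 to 0.23, 22 of 42 pairs over 0.1), against -0.0408 for other numbers (2 of 108 pairs over 0.1). WT and KO libraries numbered 1 in the same population correlated over 0.1 in 4 of 4 pairs (0.133 to 0.157), against 1 of 8 for numbers 2 and 3. What number 1 shares is not known, so WT and KO libraries need not be independent. As a hint from the data, not the design, 27 of 28 libraries had their highest mean correlation within their own genotype with their own number. With a block on the number, which joins WT and KO libraries of the same number, the count was 12 in aTreg cells. With a block on the number within each genotype the counts were 174 for thymic Treg minus CD4SP, 1 for aTreg minus rTreg and 10 for rTreg minus thymic Treg. The other 6 counts, each with its block, stayed within 1.5 times.

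Among 349 named gene results, direction and side of the threshold were kept by 348 with RLE, 332 with DESeq2, 346 with the replicate blocks and 339 without the filter. Voom kept 327 and ended the call of 18, and fits of only the groups compared kept 316 and ended 30. Over all fits that left out a library, 2112 results were kept, 211 lost the call and 6 gained it. In KO against WT, the share of reads in no gene as a covariate kept 33, ended the call of 58 and reversed 1. The myeloid covariate kept 59 and ended 35, and leaving out KO thymic Treg libraries 1 and 2 kept 24 and ended 35. For lists with at least 3 members past the test, that number fell more than 1.5-fold in 15 and stayed in 1 with the no-gene covariate. With the myeloid covariate it fell in 12, stayed in 3 and rose in 1, and without both libraries it fell in 13 and stayed in 2. Leaving out single libraries lowered it in 42 cases, kept it in 68 and raised it in 2. Adjusted over the 26 lists alone, the calls by camera were kept in KO against WT, and those by fry went from 5 to 4 in thymic Treg and from 3 to 4 in CD4SP cells. With 2.20e+07 counts in the smallest library, depth limits genes with few counts, such as Capn11.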

Other observations

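The values of cell markers, histones and single genes given here, and the test of recirculating cells, were chosen after the results were seen. NK and innate-like markers summed to 241 ± 42.3 CPM in KO thymic Treg cells and 177 ± 5.97 in WT, with 0 of 9 past the test. The higher CD8 T cell marker sum of KO thymic Treg cells was not particular to them. In rTreg cells it was 121 ± 17.5 CPM in KO and 92.9 ± 2.72 in WT, and in aTreg cells 389 ± 55.0 and 283 ± 15.6. KO and WT libraries did not overlap in any of these Treg populations, but did in CD4SP cells. Plasma cell markers summed to 264 ± 74.6 CPM in KO and 240 ± 47.6 in WT aTreg cells. Histone genes summed to 131 ± 15.6 CPM in KO and 111 ± 6.71 in WT rTreg cells.

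The X-linked gene Zcchc18, a zinc finger gene at 136993155 to 136998472, rose in 3 populations of KO cells and lies far from Foxp3. Il1rl1 ends at 40465415 on chromosome 1 and Il18r1 starts at 40465552, so these are neighbours that rose together in KO thymic Treg and rTreg cells.

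A hypothesis is that the KO thymic Treg sort held more recirculating cells of splenic type. Of 546 genes past both tests, 374 (68.5%) went the way of WT rTreg against thymic Treg cells. The WT thymic Treg libraries enter both contrasts and push the result that way, so the test does not settle whether more such cells may have been present.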
